A study of Mus musculus with 6 samples.

How the data were processed

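Messenger RNA was measured in ILC2s sorted from mouse lung, in 3 libraries labelled wild type and 3 labelled Atg5 knockout. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by the column names that the labels repeat. No column belonged to any other sample. The labels state triplicates but do not say that each came from its own mouse, so p-values measure the spread between these samples, which may be technical. Sex, litter, sort gates, day of preparation and the deleted exons of Atg5 are not given in the sources used here.

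The authors deposited a table of estimated counts per gene (18543 genes) and a table of normalized values. The submitters' processing notes name CASAVA 1.8.2, STAR, Partek and the mm10 build, with no role or order. The version they give for STAR is not one of that tool and is left out. In the deposited table, 47.1% to 48.5% of the estimated counts per library were whole numbers (within 1e-06), so reads had been shared between features. How reads that match several genes were divided, and whether strand was used, is not given in the sources used here. Values of near-identical copies (Hspa1b, Hba-a1 and Hba-a2, Tpsb2 and Tpsab1, the Tcrg constant genes, ribosomal protein genes with pseudogenes) and of overlapping or antisense genes are therefore uncertain. The second table holds what the authors call normalized counts, a signal without a fixed total. Each deposited signal equalled the estimated count plus 1, divided by 1 factor per library (31.2 to 36.0) that brought the upper quartile of every library to 52.2. It lists 16322 genes. No gene left out of it had an estimated count above 10 in any library. Gene coordinates are those of the deposited table on mm10, with the end reduced by 1 base to the last base of the gene. So read, 16826 genes matched the start and end in GENCODE vM21, and 495 symbols were absent from that release. Exons are from the same release.

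From these files, estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM library sizes, filterByExpr, glmQLFit with robust estimation, glmQLFTest) for knockout against wild type with no covariate. P-values were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. The standard error of a log2 fold change is its size divided by the square root of F. CPM are rounded counts scaled to the TMM-adjusted library size, and log2 values for correlations and components added 0.5 CPM. Library totals were 28827545 to 33662979 estimated counts, and 3 counts, the floor used for a gene at 0, are 0.0891 to 0.104 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

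Before the data were examined, 35 gene lists were fixed, 26 of cell programmes and 9 of markers of other cells, of which 34 had at least 3 tested genes. They were tested with camera (limma 3.58.1, inter-gene correlation 0.01) and adjusted over the lists. Camera compares a list with all other genes. Alternatives were camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way. With all 6 libraries no list passed with an estimated correlation (smallest adjusted p 0.679) or by fry (smallest adjusted p 0.389). Without the library labelled WT 3 again none of the gene lists passed with an estimated correlation, and 10 passed by fry. These were ILC2 identity, type 2 cytokines and effector products, NF-kappaB targets, T cell markers, and lysosome and TFEB targets. The others were nucleolar ribosome biogenesis, ribosomal protein, proteasome, antioxidant and interferon-stimulated genes. Their adjusted p by fry ranged from 0.00377 (for example ILC2 identity) to 0.0247 (antioxidant genes). The rule for named genes was also fixed before. It takes Atg5, then among genes past the threshold, separated by label and with a mean log2 CPM of at least 1, the 10 with the largest and the 10 with the smallest fold change. As none passed, it takes the 5 with the lowest p in each direction that meet the other conditions, leaving out gene models without a given name. It adds up to 4 members of each programme list past the threshold, or the 2 with the lowest p where none pass, and the 3 most abundant members of each list of other cells. Last it adds Il4, Il5, Il13, Areg, Csf2, Gata3, Rora, Il1rl1, Il7r, Klrg1 and Sqstm1. Some genes that the rule names are not reported here. Genes chosen after their values were seen are said to be so.

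Alternatives fixed before were DESeq2 size factors, upper-quartile scaling and library totals alone in place of TMM, no low-count filter, a filter of 2 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' normalized signal plus 1, non-robust dispersion, the replicate number as a block, each library left out in turn, and other thresholds. Added after the data were seen were fits without both libraries numbered 3, limma-voom with sample quality weights, DESeq2 without the library labelled WT 3, and camera with an estimated correlation and fry without that library, and fry without both libraries numbered 3. Leaving out the library labelled WT 3 was among those fixed before, and it is printed beside the main results because Atg5 goes against that label. Every test of knockout against wild type in the report keeps the groups of the labels, in some fits with libraries left out. Values per library are also set out by the clusters that were seen, such as the libraries labelled WT 1 and WT 2 against the rest. The closing section counts what other splits of the 6 libraries give.

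The edgeR fits, camera with its fixed correlation and the position measure of the closing section were tested on simulated counts. For the edgeR fits these had the real means and library sizes and 200 changed genes. The changed genes were drawn from those with a mean log2 CPM above 2. The recoveries below therefore do not cover less abundant genes, such as Tcf20 and Atcay. With all 6 libraries and the dispersions of that fit, 27% of genes changed 2-fold and 86% of those changed 4-fold were recovered, with 12 false calls among 13769 genes. Without the library labelled WT 3, 70% and 96% were recovered, with 16 false calls among 14417 genes. These false calls are set against all genes tested. Their share of the genes called, which the adjusted p is meant to limit, is larger. In both of these simulations that share lay above the threshold for the adjusted p. It would have done so even if all 200 changed genes had been recovered. The genes that edgeR called without the library labelled WT 3 may therefore include more false calls than the threshold states. With a dispersion of 0.02, all were recovered with 6 libraries. A list moved in simulation was found by camera with no other list called. In that simulation all genes were drawn independently of each other, with a dispersion of 0.02. It therefore does not show how often camera with its fixed correlation calls a list wrongly where genes move together.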

Results

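Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that lack rearranged antigen receptors and release type 2 cytokines when epithelial alarmins such as IL-33 reach them. The series measured messenger RNA in ILC2s sorted from the lungs of C57BL/6 mice aged 8 weeks, after 0.5 µg of recombinant IL-33 had been given intranasally on 3 consecutive days and the cells isolated on day 4. There were 6 libraries, 3 labelled wild type and 3 labelled Atg5 knockout, each made from 10 ng of RNA. They are called here the libraries labelled WT 1 to WT 3 and KO 1 to KO 3. The estimated counts per library summed to 30094216, 30761987 and 30111316 in those labelled WT 1, WT 2 and WT 3, and to 28827545, 33662979 and 31754420 in those labelled KO 1, KO 2 and KO 3. At these depths 3 counts correspond to 0.0891 to 0.104 CPM (counts scaled to library size), so that named genes near or below 1 CPM, such as Cd36, Itga2, Lgals7 and Itga2b, carry a large counting error in some libraries. The single comparison in the design asks how the ILC2 transcriptome differs when autophagy, which delivers cytoplasmic material to lysosomes, is impaired.

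Atg5, the targeted gene, encodes a part of the conjugation machinery that attaches LC3 to autophagosome membranes. It lies on chromosome 10, from 44268358 to 44364291 on the forward strand of the mm10 build, and its annotated protein-coding transcript has 8 exons. Its level was 66.3 and 71.8 CPM in the libraries labelled WT 1 and WT 2 but 21.8 CPM in the library labelled WT 3. In the libraries labelled KO 1, KO 2 and KO 3 it was 23.0, 25.6 and 52.2 CPM. The library labelled WT 3 therefore lay below all 3 libraries labelled knockout, and the library labelled KO 3 lay nearer to those labelled WT 1 and WT 2 than to the other libraries labelled knockout. The group means were 53.3 ± 27.4 CPM for wild type and 33.6 ± 16.1 CPM for knockout (SD, n = 3 each). The difference of -0.67 on the log2 scale (SE 0.50) did not pass the test (adjusted p = 0.478, edgeR quasi-likelihood). It was -1.03 without the library labelled WT 3 (SE 0.33, adjusted p = 0.0489). That fit is printed because of the Atg5 level in the library it leaves out, so for Atg5 itself it is no independent evidence of a loss. The counts cover the whole gene, and the labels do not say which exons the knockout lacks, so residual counts do not by themselves show intact transcript. Because the targeted gene goes against the label of at least 1 library, every direction given below is one between labels.

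**Figure D1:**
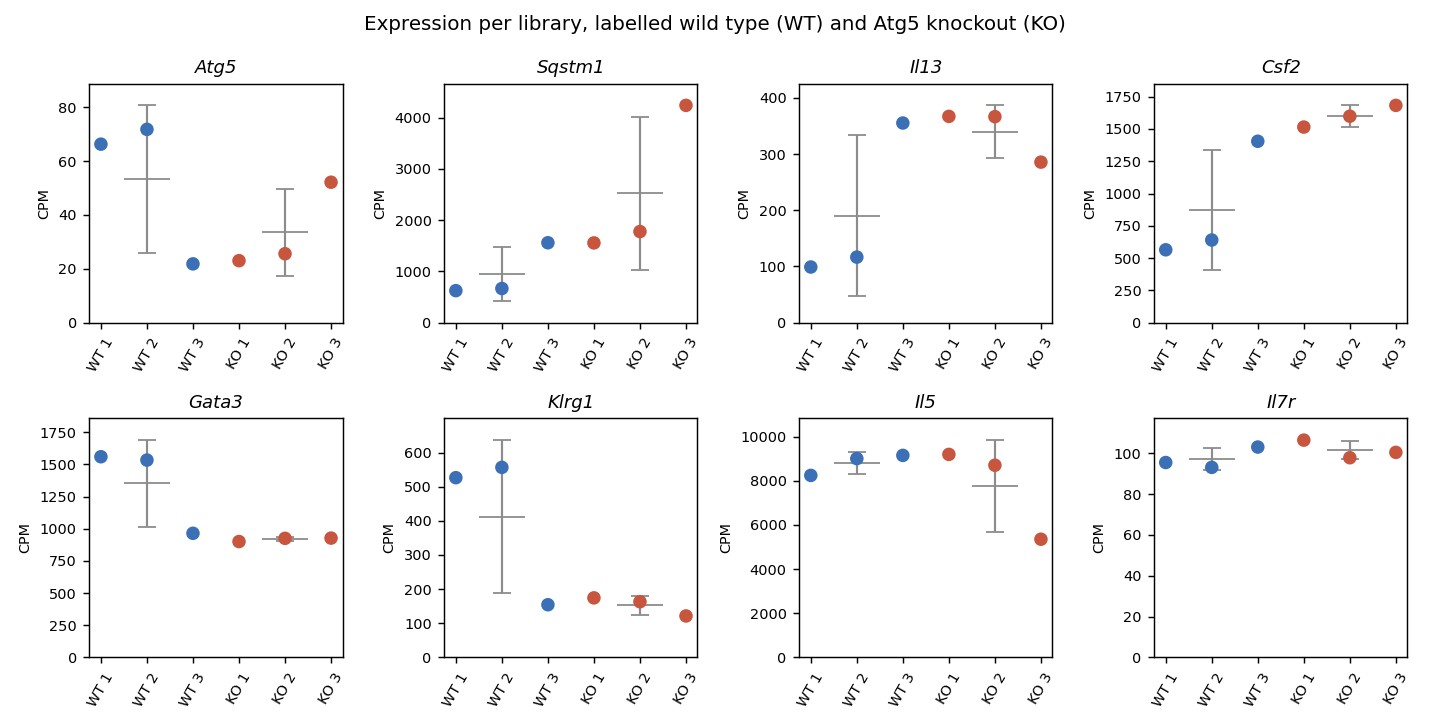
Expression of 8 genes in each library, in CPM on a linear axis that starts at 0 (blue, labelled wild type; red, labelled Atg5 knockout; grey, mean ± SD of the 3 libraries of a label). Atg5 is at 21.8 CPM in the library labelled WT 3 and at 52.2 CPM in the library labelled KO 3, and for Sqstm1, Il13, Csf2, Gata3 and Klrg1 the library labelled WT 3 lies with those labelled knockout.

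The 6 libraries fell into 3 clusters that did not match the labels. Across 14052 genes, log2 CPM correlated at r = 0.991 between the libraries labelled WT 1 and WT 2, and at r = 0.946 between those labelled WT 1 and WT 3. The library labelled WT 3 correlated at r = 0.991 with the library labelled KO 1 and at r = 0.990 with the library labelled KO 2, as closely as these did with each other (r = 0.990). The library labelled KO 3 stood apart from these 3, with r from 0.979 to 0.980. Genes are not independent replicates, so these values describe pairs of libraries. The first principal component held 70.7% of the variance and separated the libraries labelled WT 1 and WT 2 from the other 4. The second held 14.1% and set the library labelled KO 3 apart. No pair of libraries agreed within sampling noise (the chi-square per gene was at least 9.2 in every pair), so none is a resequenced copy of another, but this does not show that they come from separate mice or RNA samples.

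**Figure D2:**
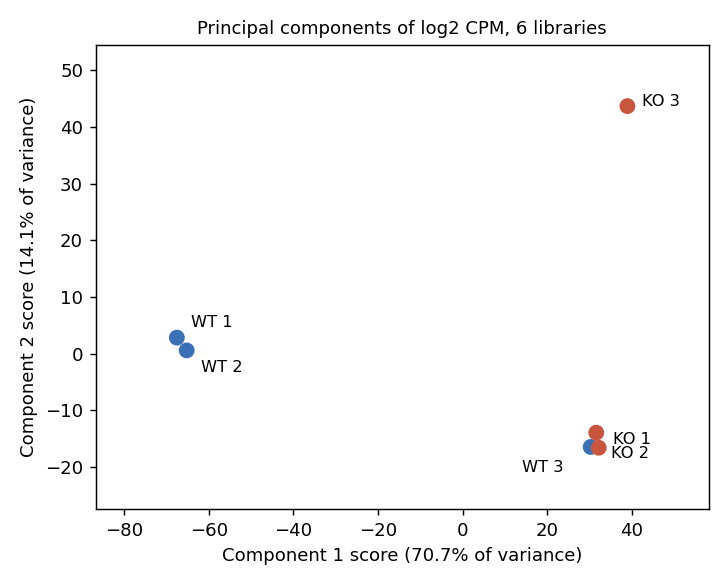
Scores of the 6 libraries on the first 2 principal components of log2 CPM (blue, labelled wild type; red, labelled Atg5 knockout; axes in score units with the share of variance). The libraries labelled WT 1 and WT 2 lie at -67.5 and -65.2 on component 1, and the library labelled WT 3 lies beside those labelled KO 1 and KO 2.

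Relative to the libraries labelled WT 1 and WT 2, those labelled knockout had more RNA for ribosome biogenesis, ribosomal proteins, the proteasome, antioxidant enzymes and the ATF4 stress programme. They also had more Il13 and Csf2, and less RNA for mitotic genes, interferon-stimulated genes, mitochondrially encoded genes and the ILC2 genes Gata3, Il1rl1 and Klrg1. None of these lists passed with an estimated correlation, and without the library labelled WT 3 the ATF4, mitotic and mitochondrial lists did not pass by fry either (adjusted p = 0.0561, 0.124 and 0.101). In the library labelled WT 3, the median member of 13 of the 14 lists called below with all 6 libraries lay between -0.19 and 0.09 log2 units from the libraries labelled KO 1 and KO 2. The exception was granulocyte and mast cell markers, at 0.59. With all 6 libraries, edgeR's quasi-likelihood test passed 0 of 14052 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.342 and 2026 genes at an unadjusted p under 0.05. DESeq2 passed 362 genes on the same counts, 20 higher and 342 lower in knockout, while limma-voom and limma-trend passed 0. In 2596 genes, 18.5% of those tested, the 3 libraries labelled knockout all lay above or all below the 3 labelled wild type. Chance gives 10% only if the 6 libraries are interchangeable. Since the libraries labelled WT 1 and WT 2 stood apart from the rest, the share cannot show an excess that follows the labels. EdgeR passed 4991 of 14743 genes without the library labelled WT 3, 2611 higher and 2380 lower, and without any one of the other 5 libraries it passed 0. Of those 4991 genes, 4937 also passed without both libraries numbered 3, an added comparison of 2 libraries with 2. In that comparison camera also placed lower 5 lists that it called neither with all 6 libraries nor without the library labelled WT 3: ILC2 identity (adjusted p = 0.00534), selective autophagy receptors (adjusted p = 0.0139), inhibitory receptors (adjusted p = 0.0264), glycolysis (adjusted p = 0.01) and p53 targets (adjusted p = 0.0256). With an estimated correlation it called none of them, while by fry all 5 passed in that comparison (adjusted p from 0.0102 to 0.0224).

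Lowest in p among the genes whose labels separated were, on the higher side, Tcf20, Acaca, Nudt6, Trmo and Dnaaf5, and on the lower side Pld1, Atcay, Wdr90, Stil and Ddias. All 10 had an adjusted p of 0.342 in edgeR's fit to all 6 libraries and none passed there, while all 10 passed by DESeq2 on the same libraries (adjusted p from 0.000676 for Pld1 to 0.0444 for Dnaaf5) and by edgeR without the library labelled WT 3 (adjusted p from 0.00118 for Stil to 0.0202 for Acaca). Acaca, which encodes the acetyl-CoA carboxylase that starts fatty acid synthesis, was at 7.11, 6.09 and 7.03 CPM in the libraries labelled WT 1, WT 2 and WT 3 and at 12.1, 12.8 and 21.8 CPM in those labelled KO 1, KO 2 and KO 3. In this gene the library labelled WT 3 had the level of the other libraries labelled wild type. Tcf20 was at 0.688 to 1.47 CPM under the wild-type label and 3.26 to 5.62 CPM under the knockout label (log2 difference 1.84, SE 0.43). Nudt6 (0.90, SE 0.23), Trmo (0.71, SE 0.19) and Dnaaf5 (0.59, SE 0.16) had smaller log2 differences. On the lower side, Pld1, a phospholipase D, was at 7.34 and 7.17 CPM in the libraries labelled WT 1 and WT 2, 4.38 CPM in the library labelled WT 3 and 1.64 to 2.08 CPM under the knockout label. Atcay (-2.69, SE 0.51), Wdr90 (-1.10, SE 0.21), Stil (-1.20, SE 0.24), which is needed for centriole duplication, and Ddias (-0.86, SE 0.18) also had the library labelled WT 3 between the others. These log2 differences are from the fit to all 6 libraries. The 10 genes were chosen for low p and separation by label in these same libraries. Passing the other fits is therefore no independent support, and the choice itself puts the library labelled WT 3 on the wild-type side.

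Cytokine transcripts of ILC2s went in different directions. Il13 was at 99.0 and 117 CPM in the libraries labelled WT 1 and WT 2, 355 CPM in the library labelled WT 3, and 367, 367 and 286 CPM in those labelled KO 1, KO 2 and KO 3. Csf2, which encodes GM-CSF, was at 564 and 640 CPM, then 1405 CPM, then 1515, 1599 and 1683 CPM in the same order. Il4 was at 24.9 and 23.4 CPM, then 8.88 CPM, then 10.5, 10.5 and 16.3 CPM. Il5, the most abundant of these cytokine transcripts, was between 8242 and 9194 CPM in all libraries except the one labelled KO 3, at 5352 CPM. None of the 4 passed with all 6 libraries (adjusted p from 0.342 to 0.688). Without the library labelled WT 3, Il13 rose by 1.66 on the log2 scale (SE 0.15, adjusted p = 0.000305) and Csf2 by 1.42 (SE 0.10, adjusted p = 0.000133), Il4 fell by 0.95 (SE 0.23, adjusted p = 0.0193), and Il5 did not pass (-0.15, SE 0.22, adjusted p = 0.65). Areg, which encodes the repair factor amphiregulin, had 298 and 330 CPM in the libraries labelled WT 1 and WT 2 and 224 CPM in the library labelled WT 3. It had 240, 223 and 131 CPM in those labelled KO 1, KO 2 and KO 3 and passed in neither fit (adjusted p = 0.366 and 0.0716). Over the list of type 2 cytokines and effector products, 0 of 22 members passed with all 6 libraries, and camera gave no call (adjusted p = 0.21). With the library labelled WT 3 left out, 11 rose and 4 fell, 16 passed when adjusted over the list alone, and camera placed the list higher (adjusted p = 0.000566, but adjusted p = 0.535 with an estimated correlation). The 2 members with the lowest p in the fit to all 6 libraries were Lgals7, at 5.84 and 6.02 CPM in the libraries labelled WT 1 and WT 2 and at most 0.744 CPM elsewhere, and Tnfsf14, which encodes the cytokine LIGHT, at 61.0 and 68.9 CPM against 30.2 to 36.7 CPM.

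Identity genes of ILC2s were mostly higher in the libraries labelled WT 1 and WT 2. Gata3, the transcription factor that sets the ILC2 programme, was at 1559 and 1533 CPM there, at 964 CPM in the library labelled WT 3 and at 900 to 927 CPM under the knockout label. Il1rl1, the IL-33 receptor, was at 973 and 924 CPM, then 471 CPM, then 432 to 527 CPM. Klrg1, a receptor of activated and inflammatory ILC2s, was at 526 and 557 CPM, then 154 CPM, then 121 to 174 CPM. Rora was at 440 and 448 CPM, then 304 CPM, then 288 to 359 CPM, while Il7r, the IL-7 receptor, stayed between 93.1 and 107 CPM in every library. In the fit that leaves out the library labelled WT 3, Gata3 fell by 0.75 (SE 0.07, adjusted p = 0.000435), Il1rl1 by 1.00 (SE 0.10, adjusted p = 0.000527), Klrg1 by 1.82 (SE 0.15, adjusted p = 0.000253) and Rora by 0.45 (SE 0.11, adjusted p = 0.0168) on the log2 scale, and Il7r did not pass (adjusted p = 0.382). Nmur1, the neuromedin U receptor, was at 209 and 217 CPM, then 76.9 CPM, then 45.8 to 69.7 CPM, and Bcl11b at 190 and 183 CPM, then 118 CPM, then 99.1 to 105 CPM. Of 25 measured identity genes, 0 passed with all 6 libraries, and 5 rose and 13 fell without the library labelled WT 3 (19 when adjusted over the list alone). Camera called this list in neither fit (adjusted p = 0.0724 and 0.0557). By fry the identity list passed without the library labelled WT 3 (adjusted p = 0.00377) but not with all 6 libraries (adjusted p = 0.389). Inhibitory receptors showed 5 members that rose and 7 that fell of 19 without that library, with no list call (adjusted p = 0.634). Cd200r1, the receptor of CD200, was at 409 and 400 CPM in the libraries labelled WT 1 and WT 2 and at 98.0 to 112 CPM elsewhere, and Vsir at 10.3 and 10.2 CPM against 3.48 to 4.05 CPM. NF-kappaB targets had 12 members that rose and 4 that fell of 24 in the same fit, a list placed higher by camera (adjusted p = 0.0281, but adjusted p = 0.774 with an estimated correlation) that was not called with all 6 libraries (adjusted p = 0.175). The members with the lowest p in the fit to all 6 libraries went the other way: Tnfrsf9, which encodes 4-1BB, was at 262 and 271 CPM against 43.1 to 60.8 CPM elsewhere, and Tnfrsf4, which encodes OX40, at 49.7 and 59.6 CPM against 11.9 to 12.9 CPM.

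The autophagy lists gave no call with all 6 libraries. Of 37 core autophagy genes 0 passed (camera adjusted p = 0.368), and without the library labelled WT 3, 1 rose and 10 fell, 7 when adjusted over the list alone, with no list call (adjusted p = 0.311). The list holds Atg5 itself, the targeted gene, which was 1 of the 10 that fell. Gabarapl1, an LC3-family gene, was the member that rose, at 43.0 and 42.2 CPM in the libraries labelled WT 1 and WT 2, 103 CPM in the library labelled WT 3, and 117, 115 and 157 CPM in those labelled KO 1, KO 2 and KO 3. Atg7, the activating enzyme of the same conjugation system as Atg5, was at 93.4 and 90.3 CPM, then 57.0 CPM, then 49.7 to 55.8 CPM. Sqstm1, which encodes the autophagy receptor p62, was at 625 and 667 CPM, then 1560 CPM, then 1557, 1779 and 4242 CPM. It did not pass with all 6 libraries (log2 difference 1.41, SE 0.52, adjusted p = 0.342) and rose by 1.97 without the library labelled WT 3 (SE 0.47, adjusted p = 0.0218). Among 20 receptors of selective autophagy and mitophagy, 3 rose and 9 fell in that fit, with no list call (adjusted p = 0.102). Calcoco1 was at 36.4 and 42.2 CPM in the libraries labelled WT 1 and WT 2 and 12.1 to 16.2 CPM elsewhere. Lysosomal genes and TFEB targets were placed lower by camera with all 6 libraries (adjusted p = 0.000621, but adjusted p = 0.679 with an estimated correlation), although 0 of 40 members passed. In the fit without the library labelled WT 3, 2 rose and 18 fell (21 when adjusted over the list alone). Tfeb, the transcription factor for lysosomal genes, was at 21.9 and 27.3 CPM against 7.24 to 8.75 CPM elsewhere.

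**Figure D3:**
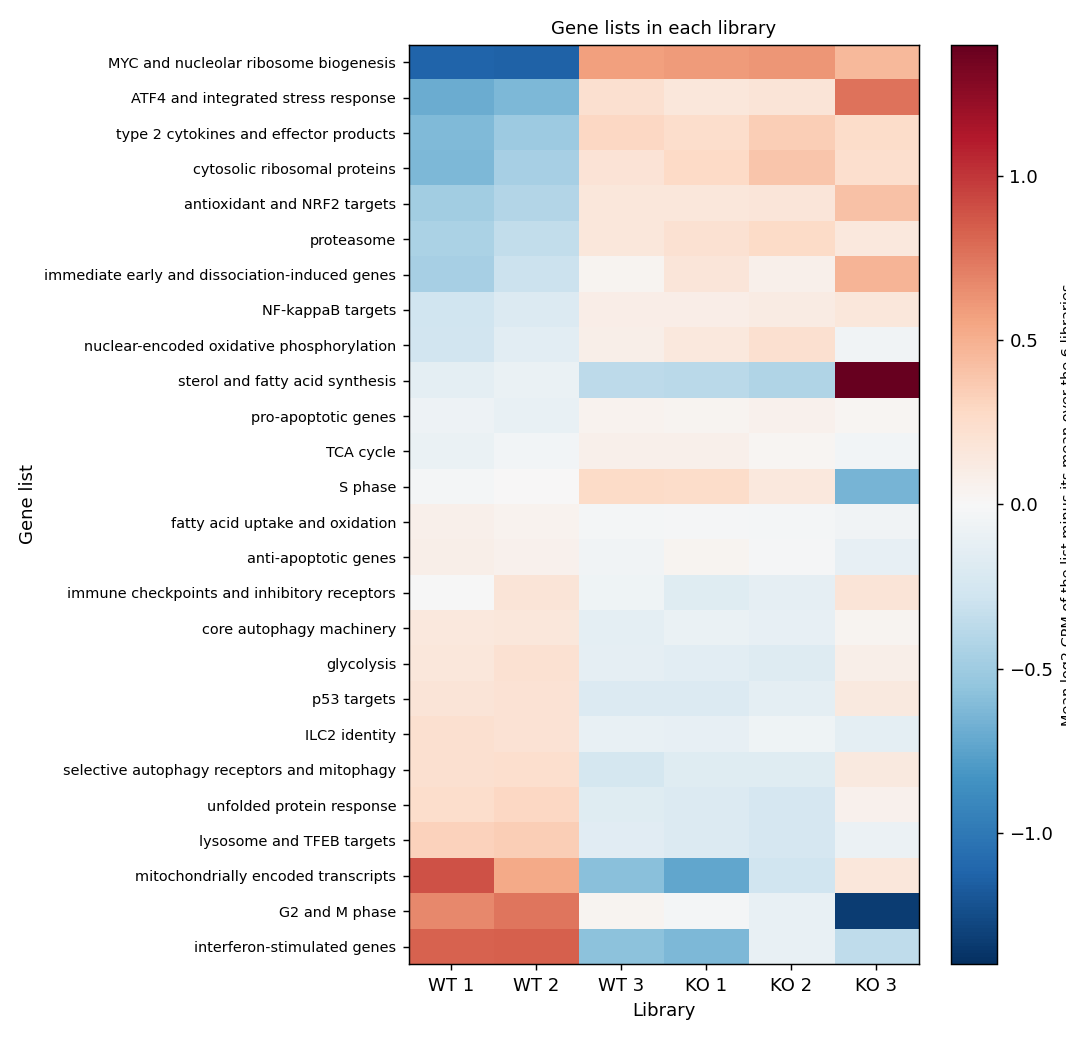
Mean log2 CPM of each of the 26 programme lists in each library, minus the mean over the 6 libraries (colour scale in log2 units, red above and blue below). The library labelled WT 3 has the colours of those labelled KO 1 and KO 2, and the library labelled KO 3 differs from these in sterol and fatty acid synthesis and the cell cycle lists, and also in mitochondrially encoded transcripts and ATF4 genes.

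Genes of protein synthesis and degradation moved together. Camera placed nucleolar ribosome biogenesis genes and MYC (adjusted p = 6e-12), cytosolic ribosomal proteins (adjusted p = 7.96e-19) and the proteasome (adjusted p = 6.49e-08) higher in knockout with all 6 libraries. None of the 3 calls held with an estimated correlation (adjusted p = 0.679 for each), and 0 members passed singly. All 31 nucleolar genes rose when the library labelled WT 3 was left out, with a median of 1.70 on the log2 scale against 0.89 with all 6 libraries. In the same fit 61 of 62 ribosomal protein genes rose (median 0.84 against 0.55 with all 6), while 31 of 36 proteasome genes rose and 1 fell. In the library labelled WT 3 the nucleolar list lay 1.75 log2 units above the libraries labelled WT 1 and WT 2 and 0.02 below those labelled KO 1 and KO 2 (medians over its members). Nip7 was at 41.1 and 43.8 CPM in the libraries labelled WT 1 and WT 2 and 116 to 136 CPM elsewhere, and Polr1a, the large subunit of RNA polymerase I, at 40.8 and 29.3 CPM against 64.6 to 73.1 CPM. Rps18 was at 381 and 475 CPM, then 644 CPM, then 742 to 811 CPM, and Rpl10a at 138 and 158 CPM, then 212 CPM, then 229 to 260 CPM. Psmb5, a catalytic subunit of the constitutive proteasome, was at 208 and 227 CPM, then 341 CPM, then 369 to 398 CPM. Psmb9, an immunoproteasome subunit, was the member that fell, from 124 and 138 CPM to between 70.5 and 78.1 CPM in those labelled knockout, with 76.5 CPM in the library labelled WT 3.

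Stress programmes parted. ATF4 and integrated stress response genes were placed higher (adjusted p = 2.23e-07), as were antioxidant and NRF2 target genes (adjusted p = 1.53e-05), and the unfolded protein response lower (adjusted p = 0.0149), with all 6 libraries. With an estimated correlation the adjusted p was 0.679, 0.679 and 0.778. The unfolded protein response list did not pass without the library labelled WT 2, KO 1 or KO 2 (adjusted p = 0.0734, 0.0558 and 0.0806), with median log2 differences of -0.18, -0.23 and -0.27 against -0.26 with all 6. Of 30 ATF4-related genes, 22 rose and none fell without the library labelled WT 3. Atf4 was at 240 and 253 CPM in the libraries labelled WT 1 and WT 2, 432 CPM in the library labelled WT 3, and 423, 443 and 683 CPM in those labelled KO 1, KO 2 and KO 3. Ppp1r15a, which encodes GADD34, was at 38.0 and 38.8 CPM, then 59.0 CPM, then 56.3, 72.7 and 147 CPM. Of 33 antioxidant genes 21 rose and 1 fell in that fit: Gclm, of glutathione synthesis, was at 144 and 157 CPM against 287 to 457 CPM elsewhere, and Ftl1, ferritin light chain, at 6188 and 6545 CPM against 11890 to 17690 CPM. Of 27 unfolded protein response genes 12 fell and none rose, among them Edem1, at 525 and 571 CPM against 186 to 218 CPM, and Pdia4, at 581 and 589 CPM against 352 to 392 CPM. Immediate early and dissociation-induced genes were placed higher with all 6 libraries (adjusted p = 0.0454, but adjusted p = 0.679 with an estimated correlation and 0.194 without the library labelled KO 3, where the median log2 difference was 0.25 against 0.27), and 16 rose and 7 fell of 32 without the library labelled WT 3. The heat shock gene Hspa1b was at 7.47 and 11.8 CPM, then 45.6 CPM, then 68.3, 53.1 and 105 CPM, and Btg2, an antiproliferative gene, at 108 and 111 CPM against 28.0 to 40.2 CPM elsewhere. Hspa1b has a near-identical neighbouring copy, so its share of the reads is uncertain. Interferon-stimulated genes were placed lower (adjusted p = 1.74e-05, but adjusted p = 0.679 with an estimated correlation), and 1 rose and 19 fell of 33 without the library labelled WT 3. Ly6a, which encodes Sca-1, was at 4068 and 4223 CPM in the libraries labelled WT 1 and WT 2 and 597 to 778 CPM elsewhere. Ifit2 was low throughout, at 2.62 to 3.71 CPM under the wild-type label and 0.862 to 1.61 CPM under the knockout label, and passed in neither fit (adjusted p = 0.342 and 0.065).

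Metabolic lists also split. Nuclear-encoded subunits of oxidative phosphorylation were placed higher (adjusted p = 0.000148) and mitochondrially encoded transcripts lower (adjusted p = 0.00387) with all 6 libraries, and both had an adjusted p of 0.778 with an estimated correlation. The mitochondrial list did not pass without the library labelled WT 1 (adjusted p = 0.121) or KO 1 (adjusted p = 0.124), with median log2 differences of -0.36 and -0.53 against -0.69 with all 6. In the fit without the library labelled WT 3, 26 of 64 nuclear-encoded subunits rose and none fell, while 8 of 15 mitochondrial transcripts fell and none rose. Without both libraries numbered 3, 48 nuclear-encoded subunits rose and 1 fell, and all 15 mitochondrial transcripts fell. Ndufs8 was at 91.4 and 92.4 CPM in the libraries labelled WT 1 and WT 2 and 141 to 153 CPM elsewhere, and Ndufc1 at 52.3 and 67.0 CPM, then 67.2 CPM, then 71.7 to 81.9 CPM. The mitochondrial transcript mt-Cytb was at 1051 and 774 CPM, then 298 CPM, then 249, 312 and 395 CPM, and mt-Atp6 at 523 and 438 CPM, then 244 CPM, then 206, 257 and 299 CPM. Mitochondrial genes together took 0.714% and 0.535% of the counts in the libraries labelled WT 1 and WT 2 and 0.23% to 0.433% in the others. Sterol and fatty acid synthesis genes were placed higher with all 6 libraries (adjusted p = 0.0139, but adjusted p = 0.778 with an estimated correlation). In the library labelled KO 3, 34 of 35 members exceeded the libraries labelled KO 1 and KO 2. Without the library labelled WT 3 the list did not pass (adjusted p = 0.651), although its median log2 difference was 0.69 against 0.81 with all 6, and 2 members passed higher and 3 lower. It turned lower without the library labelled KO 3 (median -0.30, adjusted p = 0.0309). Without both libraries numbered 3 the list was also placed lower (adjusted p = 0.0295, but adjusted p = 0.513 with an estimated correlation). Idi1, of the mevalonate pathway, was at 146 and 159 CPM, then 283 CPM, then 310, 291 and 1088 CPM. Glycolysis, fatty acid oxidation and the TCA cycle gave no list call in the fit with all 6 libraries (adjusted p = 0.148, 0.614 and 0.722) or without the library labelled WT 3 (adjusted p = 0.088, 0.634 and 0.634), though glycolysis was placed lower without the library labelled KO 3 (adjusted p = 0.0373). In the fit without the library labelled WT 3, 2 rose and 6 fell of 28 glycolysis genes, 8 rose and 9 fell of 36 fatty acid genes, and 9 rose and 4 fell of 23 TCA cycle genes. Without both libraries numbered 3, 2 glycolysis genes rose and 16 fell, 10 fatty acid genes rose and 11 fell, and 10 TCA cycle genes rose and 6 fell. The glucose transporter gene Slc2a3 was at 70.9 and 79.8 CPM against 19.1 to 26.5 CPM elsewhere, and Pfkp at 640 and 664 CPM against 310 to 344 CPM. Pcx, pyruvate carboxylase, was at 64.0 and 58.3 CPM against 18.4 to 26.8 CPM elsewhere. Eci1 was at 35.2 and 31.1 CPM, then 54.3 CPM, then 63.0 to 68.4 CPM, and Cd36 was low, at 4.07, 1.74 and 1.26 CPM under the wild-type label and at most 0.416 CPM under the knockout label.

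**Figure D4:**
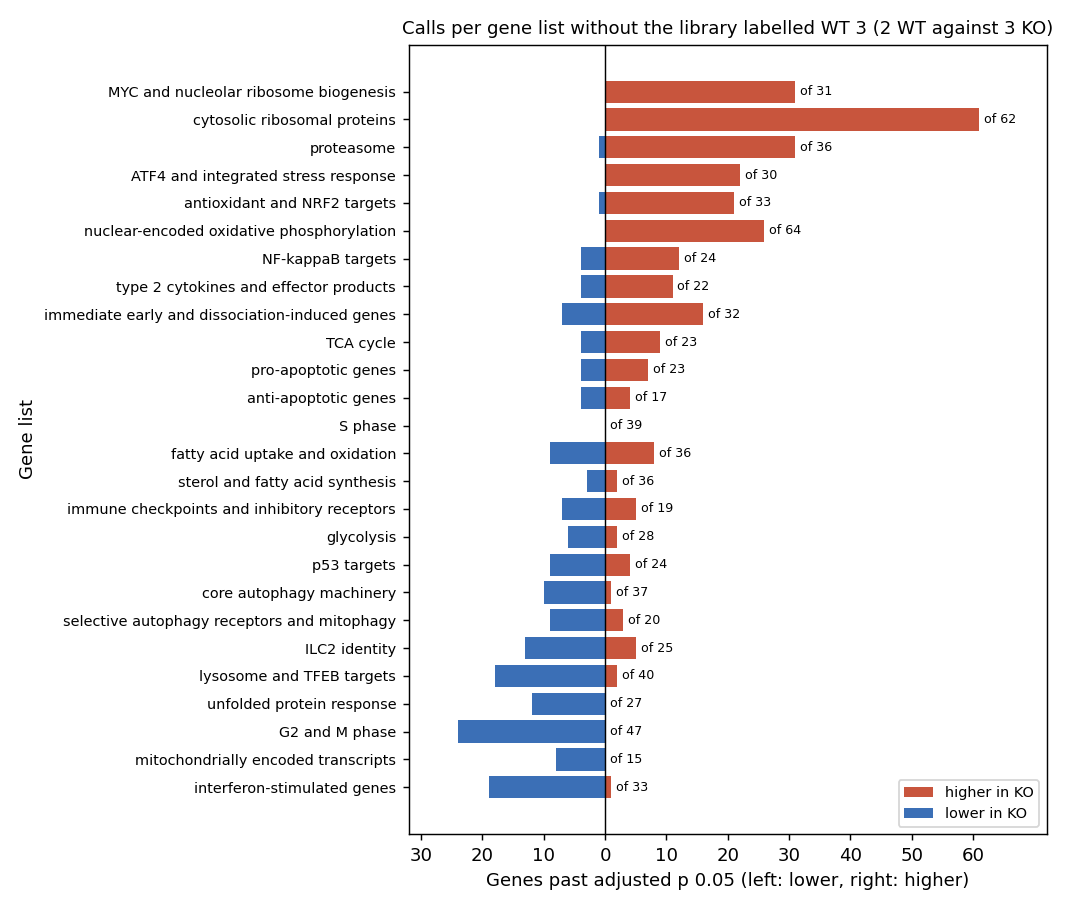
Number of members of each of the 26 programme lists past an adjusted p of 0.05 without the library labelled WT 3, 2 libraries labelled wild type against 3 labelled knockout (red, right, higher in knockout; blue, left, lower; the number measured beside each bar). With all 6 libraries every one of these counts was 0. The ribosomal protein list had 61 of 62 members higher and the nucleolar list 31 of 31.

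Mitotic genes were placed lower in knockout with all 6 libraries (G2 and M phase list, adjusted p = 7.96e-19, but adjusted p = 0.679 with an estimated correlation), with 0 of 47 members past the test. When the library labelled WT 3 was left out, 24 fell and none rose (34 when adjusted over the list alone). Without both libraries numbered 3, 43 fell and none rose. Tpx2, a spindle assembly factor, was at 240 and 235 CPM in the libraries labelled WT 1 and WT 2, 112 CPM in the library labelled WT 3, and 102, 92.6 and 49.97 CPM in those labelled KO 1, KO 2 and KO 3. Gtse1 was at 165 and 156 CPM, then 74.4 CPM, then 69.7, 61.7 and 48.3 CPM. S phase genes gave no call (adjusted p = 0.187, and 0.929 without the library labelled WT 3), and no member passed in either fit. They were placed lower when any one of the libraries labelled WT 1, WT 2, KO 1 or KO 2 was left out (adjusted p = 0.0194, 0.0437, 0.00193 and 0.0137), and higher without both libraries numbered 3 (adjusted p = 0.0476, but adjusted p = 0.659 with an estimated correlation), where 17 of 39 rose and 2 fell. Rrm2, a ribonucleotide reductase subunit, was at 693 and 711 CPM, then 513 CPM, then 488, 426 and 215 CPM, and E2f8 at 38.4 and 30.7 CPM, then 33.1 CPM, then 29.7, 23.9 and 15.7 CPM. Every measured member of both lists, 39 and 47, was lower in the library labelled KO 3 than in those labelled KO 1 and KO 2. The pro-apoptotic, anti-apoptotic and p53 target lists had no call (adjusted p = 0.964, 0.443 and 0.543), nor without the library labelled WT 3 (adjusted p = 0.634, 0.929 and 0.185), where 7, 4 and 4 members rose and 4, 4 and 9 fell of 23, 17 and 24. Casp6 was at 33.1 and 35.1 CPM in the libraries labelled WT 1 and WT 2 and 19.0 to 21.6 CPM elsewhere. Naip5 was at 42.2 and 28.2 CPM against 3.32 to 5.90 CPM, and Birc2 at 47.5 and 38.5 CPM, then 33.9 CPM, then 25.3 to 32.8 CPM.

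Markers of other cells that a lung lymphocyte sort could hold were mostly low, but several moved with the split of the libraries labelled WT 1 and WT 2 from the rest. Granulocyte and mast cell markers were the only such list called with all 6 libraries (lower, adjusted p = 0.00554, but adjusted p = 0.679 with an estimated correlation), with 2 of 9 members past the test when adjusted over the list alone and 0 over all genes. The list did not pass without the library labelled WT 3 (adjusted p = 0.135), with a median log2 difference of -1.80 against -2.08 with all 6, and 1 member rose and 4 fell. With single libraries left out, the median ranged from -2.29 (without KO 2) to -1.20 (without KO 3). These markers summed to 59.7 and 40.4 CPM in the libraries labelled WT 1 and WT 2, 25.1 CPM in the library labelled WT 3 and 13.9 to 22.7 CPM under the knockout label. Hdc, the histidine decarboxylase gene, was at 23.4 and 14.1 CPM, then 2.55 CPM, then 0.658 to 2.74 CPM. The mast cell tryptase Tpsb2 was at 4.88 to 6.92 CPM under the wild-type label and 2.59 to 7.77 CPM under the knockout label. Its paralog Tpsab1, whose reads are hard to tell from Tpsb2, was at 0.721 and 0.196 CPM, then 6.33 CPM, then 5.85 to 6.48 CPM. T cell markers summed to 857 and 944 CPM in the libraries labelled WT 1 and WT 2, 300 CPM in the library labelled WT 3 and 302 to 336 CPM under the knockout label. They were not called with all 6 libraries (adjusted p = 0.543) and placed lower without the library labelled WT 3 (adjusted p = 0.018, but adjusted p = 0.668 with an estimated correlation), with 1 member that rose and 7 that fell of 18. Among them Tcrg-C4 was at 208 and 223 CPM, then 45.4 CPM, then 26.01 to 51.3 CPM, Lat at 155 and 181 CPM, then 59.8 CPM, then 48.7 to 63.8 CPM, and Trbc2 at 143 and 159 CPM, then 105 CPM, then 120 to 124 CPM.

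The lists of the remaining other cells gave no call with all 6 libraries or without the library labelled WT 3, except that erythroid and platelet markers had too few tested genes with all 6 libraries. Markers of type 3 lymphocytes summed to 656 and 693 CPM in the libraries labelled WT 1 and WT 2 and 168 to 276 CPM elsewhere, mainly from Ltb (474 and 512 CPM against 75.7 to 178 CPM) and Lta (158 and 161 CPM against 35.0 to 46.5 CPM). Ahr went the other way, at 23.1 and 18.9 CPM against 47.4 to 56.3 CPM. Macrophage, monocyte and dendritic cell markers summed to 874 and 841 CPM against 154 to 210 CPM, of which the chemokine receptor gene Ccr2 made up 717 and 692 CPM against 54.3 to 61.7 CPM. Xcr1 was at 42.03 to 52.1 CPM and Cd74 at 25.6 to 50.4 CPM over all 6 libraries. Epithelial, endothelial and stromal markers summed to 84.0 and 71.6 CPM against 122 to 152 CPM, with Pecam1 at 10.4 and 8.54 CPM against 92.0 to 131 CPM, Epcam at 57.4 and 52.3 CPM against 8.90 to 14.3 CPM, and Hopx at 6.99 to 10.5 CPM throughout. B cell and plasma cell markers summed to 25.8 to 35.3 CPM in 5 libraries and to 243 CPM in the library labelled KO 3. Ighm, the IgM heavy chain, was at 194 CPM in that library and 7.82 to 17.3 CPM in the other 5, and Igkc at 37.0 CPM against at most 0.684 CPM, while Cd79b was at 6.38 CPM against 11.7 to 19.3 CPM. Markers of type 1 lymphocytes and NK cells summed to 17.4 to 24.5 CPM in 5 libraries and 6.54 CPM in the library labelled KO 3, with Gzmb at 7.20 to 13.0 CPM against 2.59 CPM, Cma1 at 3.80 to 7.56 CPM against 2.36 CPM, and Itga2 at 3.15 and 3.93 CPM in the libraries labelled WT 1 and WT 2 and at most 0.935 CPM elsewhere. Erythroid and platelet markers summed to 6.17 to 12.4 CPM, with Hba-a1 at 3.03 to 5.44 CPM, Hba-a2 at 1.53 to 5.15 CPM and Itga2b at no more than 0.766 CPM. The sex-linked transcripts Eif2s3y (76.9 to 89.6 CPM), Ddx3y (47.1 to 67.1 CPM) and Uty (19.8 to 29.99 CPM), all on the Y chromosome, were present in all 6 libraries.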

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

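Fits without both libraries numbered 3, with quality weights, by DESeq2 without the library labelled WT 3, and camera with an estimated correlation or fry without that library or both numbered 3, were chosen after the data were seen. The count of 0 genes from edgeR held under the other scalings, both filters, non-robust dispersion, limma-voom, limma-trend, both other thresholds, and without any library but the one labelled WT 3. DESeq2 called 362. Leaving out single libraries gave 0 to 4991 genes, the highest without the library labelled WT 3. The count of knockout versus wild type genes was 6505 without both libraries numbered 3, 6319 with sample quality weights (the library labelled WT 3 weighted at 0.15) and 5645 by DESeq2 without the library labelled WT 3. What these settings share is that the library labelled WT 3 was left out or weighted low. In the weighted fit the library labelled KO 3 also had a low weight, 0.519. DESeq2's 362 was not traced to a cause. For the replicate block, deviations of same-numbered libraries from the means of their labels correlated at -0.04, 0.02 and -0.01. The libraries labelled WT 3 and KO 3 stand apart within their labels and weigh heavily in these deviations. The values therefore show no pairing by number but cannot exclude one. The replicate block left 0 genes (1999 at an unadjusted p under 0.05), an Atg5 difference of -0.65 and 14 lists.

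The Atg5 log2 difference kept its sign throughout, from -1.12 to -0.39 when single libraries were left out, and -1.50 (without both numbered 3), -1.31 (quality weights) and -1.06 (DESeq2 without the library labelled WT 3), these 3 past the threshold. All 3 leave out the library labelled WT 3 or give it a low weight, and its Atg5 is low, so they are no independent evidence for Atg5. Of the gene lists 14 were called with all 6 libraries, 13 to 15 when single libraries were left out, 22 without both numbered 3, and 0 with an estimated correlation, with or without the library labelled WT 3. By fry, 0 passed with all 6 libraries, 10 without the library labelled WT 3 and 24 without both numbered 3. Without the library labelled KO 3 the split of higher to lower lists turned from 8 and 6 to 6 and 8, and the sterol list turned from higher (adjusted p = 0.0139) to lower (0.0309). The report names the other lists whose call changed with a single library.

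Signs turned only in genes past the threshold in none of these settings, and the cause was not tested. With all 6 libraries they lay between -0.57 (Gzmb) and 0.10 (Hba-a2). Without both libraries numbered 3 the log2 difference was 0.0078 for Gzmb, 0.21 for Cma1, 0.11 for Tpsb2, -0.33 for Hba-a2, -0.076 for Ddx3y and 0.062 for Il5. With quality weights it was 0.18 for Cma1, 0.0046 for Tpsb2 and -0.24 for Hba-a2. By DESeq2 without the library labelled WT 3 it was -0.018 for Xcr1 and -0.29 for Hba-a2. Xcr1 was at -0.0052 with no filter, -0.0070 with the stricter filter and -0.0047 by limma-trend. Leaving out single libraries gave -0.57 to 0.26 for Cma1, -0.042 to 0.11 for Xcr1, -0.77 to 0.029 for Tpsb2, -0.24 to 0.016 for Hopx, -0.26 to 0.40 for Hba-a2, -0.074 to 0.14 for Ddx3y and -0.32 to 0.030 for Il5. The lowest count among these genes was 46, for Hba-a2 in the library labelled WT 3.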

Other observations

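The tests on immunoglobulin variable genes, on gene length and GC content and on other splits for the gene lists were set before their results were seen, and the other tests in this part after. The genes in this paragraph and the next were chosen after their values were seen. Il6 was at 2.03 and 1.31 CPM in the libraries labelled WT 1 and WT 2, 55.2 CPM in the library labelled WT 3 and 69.0, 57.8 and 96.3 CPM in those labelled KO 1, KO 2 and KO 3. Arg1, the arginase 1 gene, was at 510 and 551 CPM, then 179 CPM, then 198, 172 and 108 CPM. Tcrg-C1, a T cell receptor gamma constant gene, was at 235 and 256 CPM, then 6.03 CPM, then 5.44, 6.72 and 4.02 CPM, and Il22 had 0 counts in the libraries labelled WT 1 and WT 2 and 1.24 to 4.31 CPM in the other 4. Without the library labelled WT 3 the log2 differences were 5.48 for Il6 (SE 0.33), -1.73 for Arg1 (SE 0.23) and -5.50 for Tcrg-C1 (SE 0.20), with adjusted p of 8e-05, 0.0014 and 2.1e-05 (edgeR quasi-likelihood). With all 6 libraries none of the 3 passed (adjusted p of 0.426, 0.342 and 0.342). The fitted value for Il22 depends on the prior count and is not given.

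The library labelled KO 3 carried a sterol and cell cycle profile of its own. Hmgcs1, the HMG-CoA synthase gene of the mevalonate pathway, was at 1527 CPM there and 162 to 255 CPM in the other 5 libraries. Insig1 was at 350 CPM against 62.9 to 109 CPM, and Sqle at 597 CPM against 187 to 212 CPM. The median member of the sterol and fatty acid synthesis list was 1.86 log2 units above the libraries labelled KO 1 and KO 2, and the medians of S phase and of G2 and M phase genes were -0.86 and -1.28 log2 units from them. The proliferation marker Mki67 was at 45.7 CPM against 102 to 189 CPM.

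The first pattern is that the library labelled WT 3 lies with those labelled KO 1 and KO 2. No explanation tested is argued against here: for an exchange of labels with the library labelled KO 3 the values conflict, since over 2657 genes past the threshold and at least 2-fold apart between the libraries labelled WT 1 and WT 2 (position 0) and KO 1 and KO 2 (position 1), the library labelled KO 3 lay at a median of 0.954 (quartiles 0.743 and 1.17) but its Atg5 at 0.269, and the exchange needs both under 0.5. A single wrong label on the library labelled WT 3 remains a candidate explanation: it lay over 2-fold outside both of those labelled KO 1 and KO 2 in 47 of 11817 genes, against 61 and 53 genes for these in turn, and its Atg5 level was below theirs. A library batch cannot be told apart from this, since the 3 clusters are runs of consecutive library numbers (9 and 10, 11 to 13, and 14), but 0.1 of all arrangements would give such runs. A wild-type mouse whose ILC2s had reached the state seen in those labelled knockout also stays open and was not tested, as the labels tie no library to a mouse.

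The second pattern is that the library labelled KO 3 differs from those labelled KO 1 and KO 2 in sterol synthesis, cell cycle, Atg5 and immunoglobulin genes, and also in mitochondrially encoded transcripts (median 0.74 log2 units higher, 14 of 15 above) and ATF4 genes (0.67 higher, 27 of 30 above). Admixture of ILC2 RNA like that of the libraries labelled WT 1 and WT 2 is argued against: its Atg5 level would need a position of 0.377 on the linear axis, and the median gene lay at 0.967 (lower quartile 0.739). Gene length and GC content are argued against as well for the sterol list, whose median was 1.86 before and 1.85 after their trend was removed. The S phase median went from -0.856 to -0.866, and that of G2 and M phase stayed at -1.28, though the prediction set before concerned the sterol list alone. The trend explained 0.347% of the variance. Atg5, immunoglobulin, mitochondrially encoded and ATF4 genes were not examined in this way. For the immunoglobulin genes alone, RNA from plasma cells is a candidate source: immunoglobulin variable genes summed to 31.0 CPM, 68.9 times the highest other library, and Jchain was at 4.40 CPM against at most 0.133 CPM, beside Ighm at 194 CPM and Igkc at 37.0 CPM, while the B cell gene Cd79b was not raised (6.38 CPM against 11.7 to 19.3 CPM) and the sort gates that would remove such cells are not given. No biological explanation for these differences was tested, since the labels set this library apart by nothing but its number.

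With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. By label edgeR passed 0 genes (DESeq2 362) and the highest other split gave 1; any of the 10 splits reaches a count of 0, so this comparison shows nothing about chance. By label 14 lists were called, and 2 of the 10 splits, the labels included, gave as many, with 14 also the highest of the others. That other split exchanged the libraries labelled WT 3 and KO 3 and had 3044 genes at an unadjusted p under 0.05, against 2026 by label. The splits that kept the libraries labelled WT 1 and WT 2 together had 1717 to 3044 such genes and those that parted them 54 to 85, which points to a structure of the samples that the labels do not follow. Camera with its fixed correlation called 12 to 14 lists in the former splits and still 7 to 10 in the latter. Several lists were thus called under any grouping, so a low adjusted p from this test does not by itself show a difference by label.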
